A study of Mus musculus with 12 samples.

How the data were processed

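RNA from visceral white adipose tissue of FVB/N mice was measured in 12 libraries, 3 in each of 4 groups that cross genotype (wild type, carrying the cardiac tTA driver alone, or transgenic for heart-specific TGF-b1) with diet (control or high-fat). Group and replicate number were taken from the sample titles and match the genotype and diet labels. The labels' protocols give a Zymo column kit for the RNA and the BGI DNBseq method for the libraries. Replicate numbers were used to name the libraries and not to pair them.

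The authors deposited a read count per gene for each library, as whole numbers that had not been normalized. Per the submitters' processing notes, HISAT2 2.2.0, HTSeq 2.0 and DESeq2 1.32.0 were used with the mm10 genome build. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads from a gene and an overlapping gene on the opposite strand cannot be told apart. Each count file held 50559 gene symbols and 5 summary entries for reads not assigned to a gene. Those summary entries, which held 16.8% to 21.0% of all reads (6.72% to 11.8% aligned to more than 1 place, 3.02% to 3.87% outside genes, 2.54% to 2.88% ambiguous between genes), stayed out of library sizes and tests. Reads that align to several places are not counted per gene by these rules, so members of near-identical gene families are measured low and their values are less certain.

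The authors also deposited a results table for each of the 4 pairwise comparisons, per the file headers from DESeq2. These tables give a mean normalized count, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value per gene, all computed by the authors. Running DESeq2 1.42.0 on the 6 libraries of each comparison gave the same calls as the deposited tables in each of the 4 comparisons. Those tables serve here only as a reference beside the refitted values, and are named where they are quoted.

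Library totals over genes ran from 20.1 to 21.3 M counts (median 20.9 M), and 22603 to 23720 genes had at least 1 count in a library. The 50 most abundant genes took 24.6% to 32.1% of the counts, and mitochondrially encoded genes took 4.56% to 11.9%. Pairs of libraries differed by far more than counting noise (chi-square per degree of freedom of at least 25.1 over all pairs), so no library was treated as a second copy of another.

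Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the filterByExpr function with its minimum count of 10 and minimum total of 15, which left 16550 genes. TMM factors scaled the libraries, and a group-means model of all 12 libraries, with 8 residual degrees of freedom and no other terms, was tested with the quasi-likelihood F test. The biological coefficient of variation was 20.1%. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. The 5 comparisons were diet within each genotype, transgene within each diet, and the genotype by diet interaction, which is the diet effect in transgenic tissue minus that in wild-type tissue. CPM values, which are counts relative to the library total, were scaled by the TMM factors, and log CPM values used a prior count of 2. Counting intervals of ratios are 95% exact intervals and cover counting error only, because reads without molecular identifiers are not independent molecules.

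The 45 gene lists, the design, the rule for naming genes and the alternatives, apart from those given below as added, were fixed before the data were examined. The lists cover adipocyte metabolism, TGF-beta signalling, matrix, immune and stromal cell types, other tissues that a dissection could include, and stress states. The 41 lists with at least 5 measured genes were tested with camera from limma 3.58.1 at its preset correlation of 0.01 between genes, adjusted over those lists. Camera with an estimated correlation and the fry test were run beside it. Named genes are the 10 with the largest rise and the 10 with the largest fall among called genes with at least 1 CPM in the higher group and no overlap between the libraries compared, leaving out predicted genes. Where fewer than 5 genes passed, the 5 with the smallest p are named. A fixed panel of 21 genes and up to 4 members of each list with the smallest p complete the named genes. A list's genes were also counted after adjustment over the list alone.

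Symbols were matched to the RefSeq table of GRCm38.p6, the assembly that mm10 denotes, for 48908 symbols (96.7%), and coordinates come from that table. Overlaps of exons were computed from the GENCODE annotation of the same assembly. Art2a is absent under that symbol from the exon annotation and has a close paralog, Art2b, so its value is uncertain.

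Alternatives were DESeq2 and limma-voom with quality weights on all 12 libraries, no filter beyond 1 count, a filter of at least 1 CPM in 6 libraries, size factors by other methods, only the 6 libraries compared, a replicate block, stricter thresholds, and leaving out each library in turn. Leaving out the 2 libraries rich in mammary transcripts, or the 2 rich in skeletal muscle transcripts, was added after the data were seen. The fit was tested on simulated counts of 16550 genes with known changes: for diet in wild type it recovered 16.4% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 92.4% of those changed 4-fold. For the interaction these shares were 1.5%, 37.3% and 74.2%.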

Results

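RNA of visceral white adipose tissue was sequenced from mice of 4 groups, with 3 libraries in each. Wild-type mice here carried only the tTA driver under the cardiac alpha-myosin heavy chain promoter, and transgenic mice carried that driver together with a TGF-b1 transgene expressed in the heart. Each genotype received control chow (17% of energy from fat, 3.1 kcal/g) or a high-fat diet (60% of energy from fat, 5.21 kcal/g). The mice were 8 to 10 weeks old when high-fat feeding was given, and it lasted 2 or 6 weeks, but the labels do not say which duration belongs to which library. The design asks how adipose tissue responds to the diet, and whether TGF-b1 made in the heart alters adipose tissue or that response. The libraries held 20.1 to 21.3 M gene counts each, and 16550 genes entered the tests. The labels do not say that each library came from a separate mouse, so the p-values measure the spread between these libraries, which may be technical in part. Xist, transcribed from the inactive X chromosome, lay between 270.5 and 402 CPM in the 12 libraries. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y did not pass the filter on low counts. Both are the pattern of female tissue, although the labels give no sex. The first principal component took 28% of the variance and separated the 6 control-diet libraries from the 6 high-fat libraries.

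Tgfb1, the gene overexpressed in the heart of the transgenic mice, was measured in the adipose tissue of every group. Its level was 46.5 ± 1.08 CPM in wild type on control diet, 66.8 ± 2.80 CPM in wild type on high-fat diet, 56.6 ± 5.28 CPM in transgenic on control diet and 77.7 ± 4.05 CPM in transgenic on high-fat diet (SD, n = 3 each). The gene lies at chromosome 7, 25687002 to 25705077 (GRCm38), and reads of the transgene and of the endogenous gene could not be told apart. High-fat diet raised Tgfb1 in wild type (log2 fold change 0.52, SE 0.09, adjusted p = 0.0244) and in transgenic tissue (0.46, SE 0.09, adjusted p = 0.0106). The wild-type call was lost without any 1 of control replicates 1 and 2 and the 3 high-fat libraries (log2 0.50 to 0.55, adjusted p up to 0.117). The transgene difference did not pass on either diet (0.28, SE 0.09, adjusted p = 0.274 on control diet, and 0.22, SE 0.09, adjusted p = 0.714 on high-fat diet). No transgenic library overlapped a wild-type library of the same diet. Because the transgene acts in the heart, the adipose level of Tgfb1 does not check the genotype labels. Myh6, the cardiac myosin heavy chain gene, lay at 0.547 to 1.58 CPM on average in the 4 groups.

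Some libraries held transcripts of tissues other than fat. The mean of the 6 measured genes of the mammary epithelial list was 2.59 in wild-type control replicate 1 and 3.77 in transgenic control replicate 2. This is on the log2(CPM + 1) scale, against 0.50 to 1.08 in the other 10 libraries. These genes were Krt5, Krt14, Trp63, Epcam, Cdh1 and Cldn3, which many epithelia share. The milk protein genes Csn1s1, Csn2, Csn3, Wap and Lalba did not pass the filter, so the epithelium was not shown to be mammary. The 2 libraries are called mammary-rich after the list's name. The mean of 13 skeletal and cardiac muscle genes was 4.05 in wild-type high-fat replicate 3 and 4.22 in transgenic control replicate 3, against at most 1.68 in the others. Liver genes stood at 5.74 in wild-type high-fat replicate 2, against at most 4.18 elsewhere, and Schwann cell genes at 3.92 in wild-type control replicate 1, against at most 2.97 elsewhere.

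**Figure D1:**
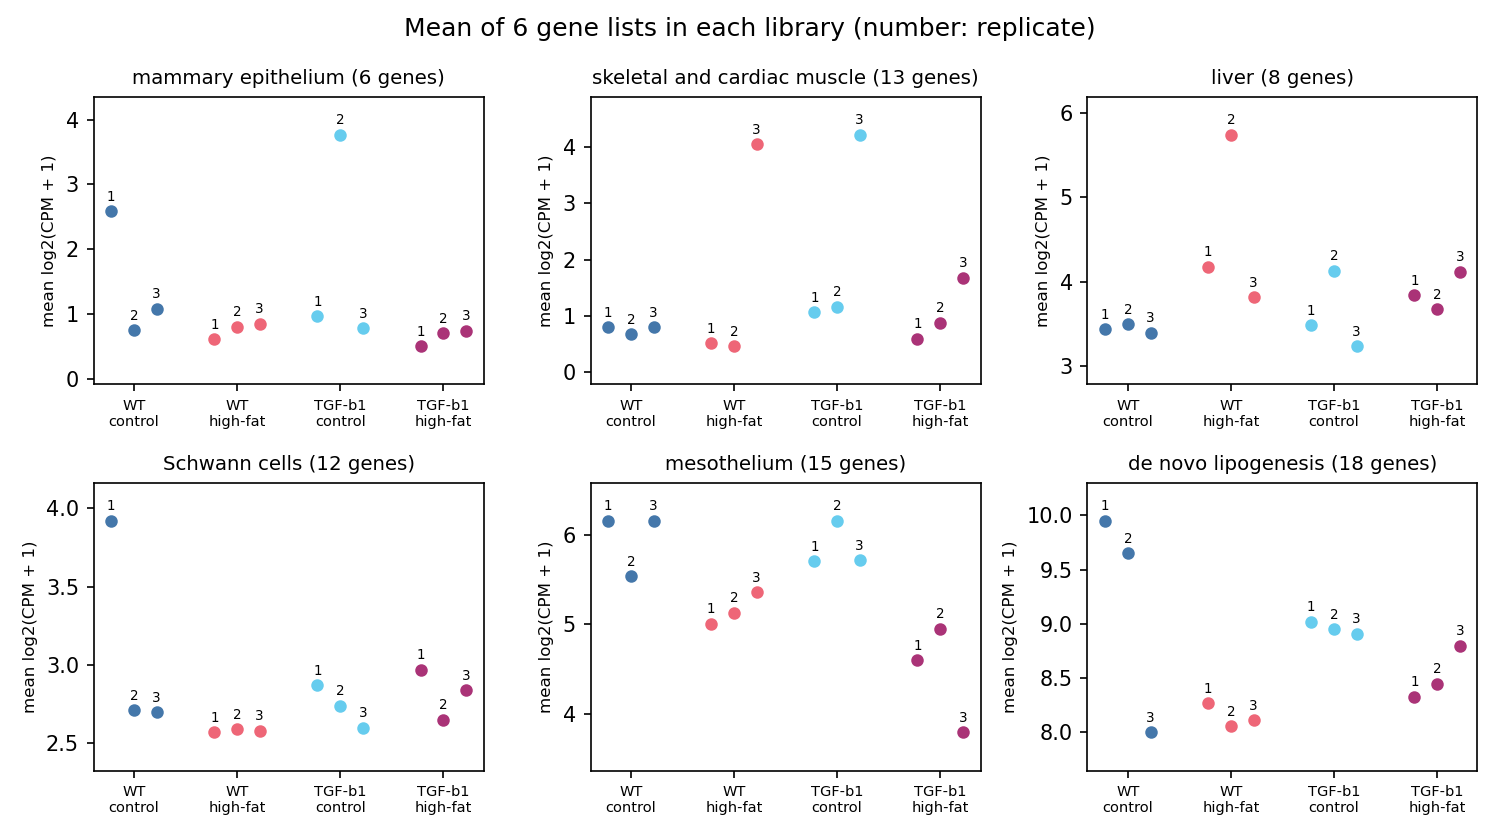
Mean log2(CPM + 1) of 6 gene lists in each of the 12 libraries, by group, with the replicate number above each point. Genes of the mammary list stand out in wild-type control replicate 1 (2.59) and transgenic control replicate 2 (3.77). Muscle genes do so in wild-type high-fat replicate 3 (4.05) and transgenic control replicate 3 (4.22), and mesothelial means are lower in the high-fat groups.

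In wild-type mice, high-fat diet raised the list of inflammatory cytokine and chemokine genes. Camera also called cell cycle and matrix lists up and de novo lipogenesis down, and these calls were lost when the correlation was estimated (adjusted p = 0.151, adjusted p = 0.151 and adjusted p = 0.265 with an estimated correlation). Ccl2, a chemokine that draws monocytes into tissue, rose from 4.32 ± 1.07 to 18 ± 3.1 CPM (SD, n = 3 each; log2 2.05, SE 0.29, adjusted p = 0.0178). Itgax, an integrin chain of dendritic cells and of macrophages in obese fat, rose from 2.41 ± 0.341 to 10.2 ± 5.56 CPM (2.08, SE 0.35, adjusted p = 0.0244). Acacb, which encodes the mitochondrial isoform of acetyl-CoA carboxylase, was lowered from 374 ± 165 to 83.2 ± 21.9 CPM (-2.17, SE 0.38, adjusted p = 0.0249). All 3 calls were lost without control replicate 1, control replicate 2, high-fat replicate 1 or high-fat replicate 2, and that of Acacb also without high-fat replicate 3 (adjusted p up to 0.0915, 0.102 and 0.137 for Ccl2, Itgax and Acacb). By edgeR's quasi-likelihood test 188 genes passed, 113 raised and 75 lowered, and 2991 had an unadjusted p under 0.05 against 828 expected by chance. Of 41 gene lists camera called 23 at its preset correlation (11 up, 12 down), and 1, cytokines and chemokines, held with an estimated correlation. Dividing the same wild-type libraries into other groups of 3, which mix the diets, gave up to 20 called lists.

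The inflammatory cytokine and chemokine list had 5 of its 15 measured genes raised and none lowered (adjusted over the list alone, 9 raised and 1 lowered). Its median log2 change was 1.18 (camera adjusted p = 8.93e-13, and adjusted p = 0.00168 with an estimated correlation). Its leading members were Ccl7 (1.82, SE 0.20), Ccl2, the neutrophil chemokine Cxcl1 (2.58, SE 0.38) and Ccl8 (1.95, SE 0.32). Of 25 cell cycle genes 3 passed, namely Bub1 (3.12, SE 0.51), Mcm6 (1.38, SE 0.28) and the proliferation marker Mki67 (1.31, SE 0.27). Adjusted over the list alone 16 were raised. The list's median was 0.97 (camera adjusted p = 2.68e-13, adjusted p = 0.151 with an estimated correlation). Of 27 matrix genes 4 rose, the collagens Col6a2 (1.39, SE 0.21), Col6a1 (1.07, SE 0.21) and Col15a1 (0.86, SE 0.18) and the metalloproteinase inhibitor Timp1 (2.21, SE 0.46). That list had 12 raised and 1 lowered when adjusted over the list alone. Cxcl1, Bub1 and Timp1 did not pass without control replicates 1 or 2 or any 1 of the high-fat libraries (adjusted p up to 0.102, 0.111 and 0.169). The matrix median was 0.49 (camera adjusted p = 2.05e-09, adjusted p = 0.151 with an estimated correlation). Among 14 dendritic cell genes, Cd74 (0.91, SE 0.17), which chaperones class II antigen presentation, and Fscn1 (0.83, SE 0.17) rose; adjusted over the list alone 7 did. Their median was 0.71 (camera adjusted p = 5.05e-07, adjusted p = 0.151 with an estimated correlation). T and NK cell genes had 0 of 15 calls by edgeR. Their median was 0.73 (camera adjusted p = 0.00123, adjusted p = 0.42 with an estimated correlation), and without control replicate 3 the T and NK cells list was not called (median 0.48, adjusted p = 0.0871).

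All 18 de novo lipogenesis genes had a negative log2 change. Their median was -1.35 (camera adjusted p = 5.15e-12, adjusted p = 0.265 with an estimated correlation). Acacb and Thrsp (-2.57, SE 0.55, adjusted p = 0.0448), a promoter of lipogenic transcription, passed over all genes tested, and 14 were lowered when adjusted over the list alone. Fasn, encoding fatty acid synthase, went from 12200 ± 8990 to 3420 ± 752 CPM (-1.83, SE 0.57, adjusted p = 0.124), and Acly from 2280 ± 2150 to 363 ± 67.6 CPM (-2.65, SE 0.83, adjusted p = 0.125). Their wide control spread came with a low lipogenic list mean in wild-type control replicate 3, 8.00 on the log2(CPM + 1) scale against 9.95 and 9.65 in replicates 1 and 2, and 8.06 to 8.27 in the high-fat libraries. Without wild-type control replicate 1 the list's median was -0.78. Nuclear-encoded oxidative phosphorylation genes had 0 of 26 calls by edgeR. Their median was -0.42 (camera adjusted p = 3.13e-11, adjusted p = 0.394 with an estimated correlation). Pnpla2, the adipose triglyceride lipase, was lowered (-0.64, SE 0.13, adjusted p = 0.0411; called in 3 of the 12 fits without 1 library), as was Pik3r1, a regulatory subunit of the kinase downstream of the insulin receptor (-1.18, SE 0.17, adjusted p = 0.0178). The adipokine Lep stood at 1600 ± 351 and 2300 ± 416 CPM on the 2 diets, a difference that did not pass (0.53, SE 0.27, adjusted p = 0.323). Adipoq (-0.29, SE 0.17, adjusted p = 0.388), Plin1 (-0.03, SE 0.12, adjusted p = 0.918) and Pparg (-0.24, SE 0.12, adjusted p = 0.337), markers of the adipocyte itself, did not pass either.

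Among stromal lists, mesothelial genes, of the cell layer that covers visceral fat, had 0 of 15 calls over all genes and 6 lowered when adjusted over the list alone. Their median was -0.86 (camera adjusted p = 9.03e-08, adjusted p = 0.265 with an estimated correlation). Of 8 erythroid genes Hba-a1 was lowered (-1.18, SE 0.24, adjusted p = 0.0411), and 7 were lowered when adjusted over the list alone. Their median was -1.12 (camera adjusted p = 5.63e-08, adjusted p = 0.151 with an estimated correlation). Adipose expansion markers, genes reported to rise in growing fat such as Npr3 and Cavin1, had 0 of 12 calls over all genes, 4 raised when adjusted over the list alone. Their median was 0.53 (camera adjusted p = 1.68e-05, adjusted p = 0.151 with an estimated correlation). Liver genes had a median of 2.80 (camera adjusted p = 0.000861, adjusted p = 0.327 with an estimated correlation), with 0 of 8 called over all genes, 6 raised and 1 lowered when adjusted over the list alone. Gc, a liver plasma protein gene with 336 counts on high-fat and 2 on control diet (ratio 159, 95% counting interval 43.7 to 1320), stood at 13.6 CPM in the liver-rich high-fat replicate 2, against 0.756 and 0.511 CPM in the other high-fat libraries. Its log2 change was 4.06 without that library, and its call was lost whichever of the 12 libraries was left out (adjusted p up to 0.166). Schwann cell genes had a median of -1 (camera adjusted p = 0.0103, adjusted p = 0.42 with an estimated correlation), beside the high Schwann mean of wild-type control replicate 1. Without that library the median was -0.23 and the list was not called, and without high-fat replicate 2 the liver median was 1.76.

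The other genes with the largest rises in wild type were Sirpb1a (3.18, SE 0.66), Gas2l2 (2.86, SE 0.45), Mageb18 (2.65, SE 0.45), Cdkl4 (2.58, SE 0.43), Mcm10 (2.2, SE 0.38), a replication factor, and Pclaf (2.09, SE 0.35), a partner of the sliding clamp in DNA synthesis. Among the largest falls were those of Alox15 (-2.75, SE 0.36, adjusted p = 0.0178), an arachidonate lipoxygenase, Cish (-2.50, SE 0.50), a suppressor of cytokine signalling, and Prrt4 (-2.49, SE 0.48). Mc5r (-2.34, SE 0.44), a melanocortin receptor, Bcas1 (-2.11, SE 0.39), Timp4 (-2.10, SE 0.38), the Wnt ligand Wnt2b (-1.78, SE 0.30) and Ripk4 (-1.73, SE 0.30) followed. Cish and Bcas1 share 11.5% and 12.6% of their exon bases with genes on the other strand, so their values are uncertain. Cish stood at 43.8 CPM in control replicate 3 against 15.8 and 8.43 CPM in the other controls, and its change was -1.59 without that library (adjusted p = 0.0452). None of the genes of this paragraph passed without control replicate 1, high-fat replicate 1 or high-fat replicate 2. Without high-fat replicate 3 Alox15 alone of them passed, and without control replicate 2 Alox15, Cish and Ripk4 did. Sirpb1a, Cish and Prrt4 were lost without some further libraries as well, passing in 4, 6 and 6 of 12 such fits. Alox15 lies at chromosome 11, 70344147 to 70390538, and Wnt2b at chromosome 3, 104944805 to 104961709 (GRCm38).

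The number of wild-type diet calls rested on single libraries, falling from 188 to 2, 13, 9, 0 and 17 without control replicate 1, control replicate 2, high-fat replicate 1, high-fat replicate 2 and high-fat replicate 3, and rising to 269 without control replicate 3. It was 32 without both mammary-rich libraries and 23 without both muscle-rich libraries, 847 with DESeq2 and 699 with limma-voom, while the authors' deposited table calls 1011 genes.

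**Figure D2:**
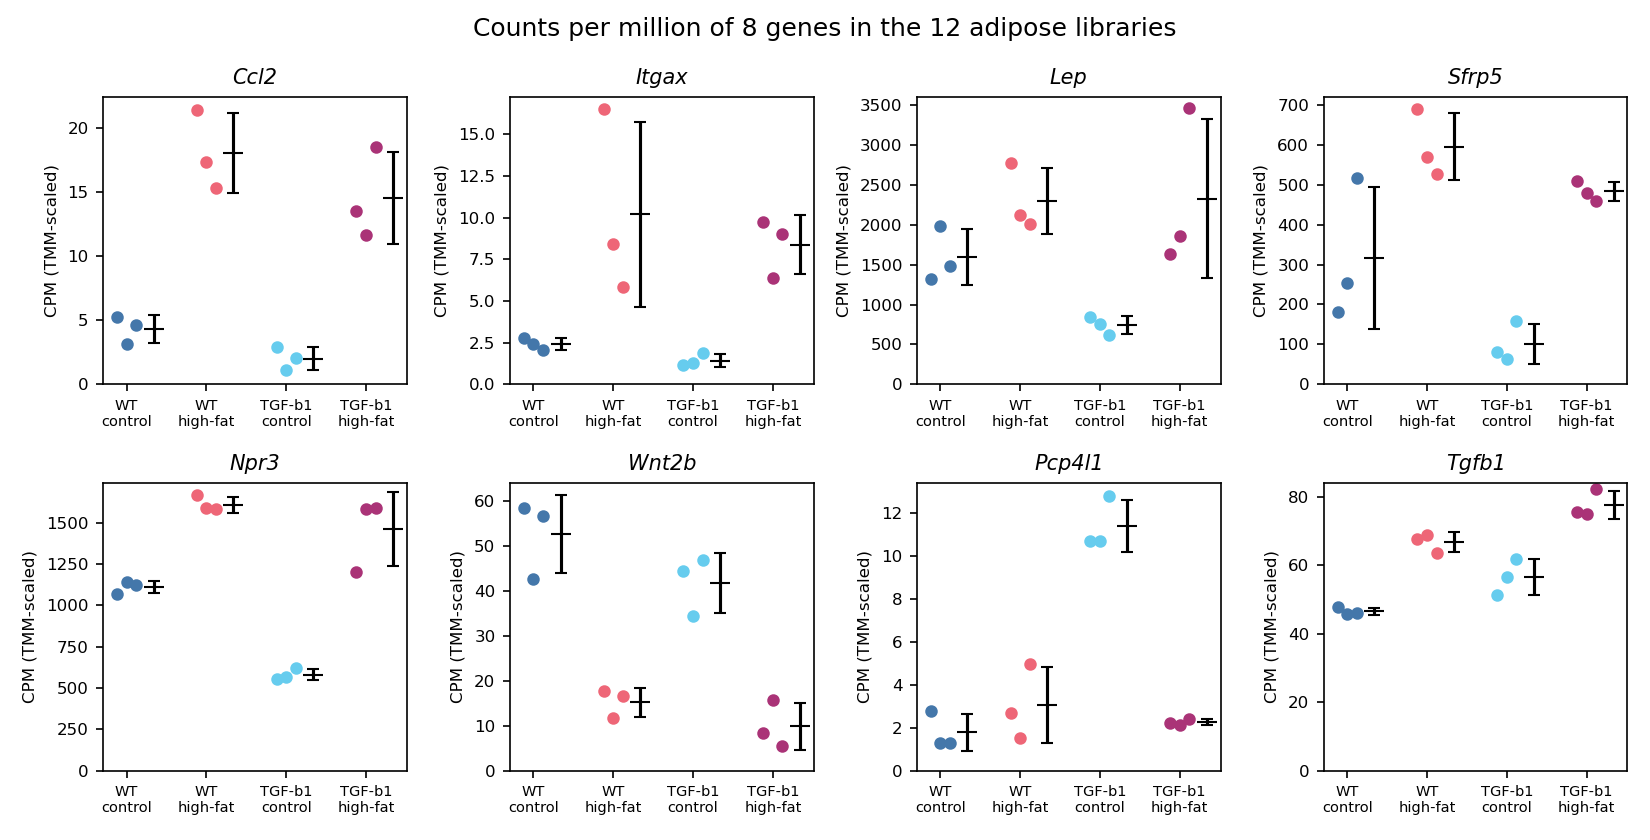
CPM (TMM-scaled) of 8 genes in the 12 libraries, with points for libraries and the mean ± SD of 3 libraries beside them. Ccl2 and Itgax are higher on high-fat diet in both genotypes, and Pcp4l1 stands at 11.4 CPM in the transgenic control group against 1.78, 3.05 and 2.24 CPM in the other groups.

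In transgenic mice, high-fat diet raised the list of inflammatory cytokine and chemokine genes. Camera also called cell cycle, dendritic cell and adipose expansion lists up and mesothelium down, and these calls were lost when the correlation was estimated (adjusted p from 0.0919 to 0.102 with an estimated correlation). Lep, the hormone secreted in proportion to fat mass, rose from 745 ± 114 to 2330 ± 1000 CPM (SD, n = 3 each; log2 1.64, SE 0.27, adjusted p = 0.00516). Sfrp5, a secreted Wnt antagonist made by fat, rose from 101 ± 51.0 to 483 ± 24.8 CPM (2.25, SE 0.38, adjusted p = 0.00546). Npr3, the clearance receptor of natriuretic peptides, rose from 581 ± 34.1 to 1460 ± 225 CPM (1.33, SE 0.13, adjusted p = 0.000439). By edgeR's test 1445 genes passed, 892 raised and 553 lowered, and 4278 had an unadjusted p under 0.05. Camera called 17 of 41 lists (8 up, 9 down), of which cytokines and chemokines alone held with an estimated correlation. Dividing the same transgenic libraries into groups of 3 that mix the diets gave up to 19 called lists. The number called therefore does not set the diets apart.

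Of 15 inflammatory cytokine and chemokine genes 10 rose (adjusted over the list alone, 12 raised and 2 lowered). Their median was 1.40 (camera adjusted p = 1.83e-10, and adjusted p = 0.00369 with an estimated correlation). They included Ccl2 (2.85, SE 0.31, adjusted p = 0.000836), Ccl7 (2.31, SE 0.21), Saa3 (3.41, SE 0.55), an acute-phase protein made in inflamed fat, and Cxcl1 (1.85, SE 0.38). Of 25 cell cycle genes 17 rose (adjusted over the list alone, 21). Their median was 1.54 (camera adjusted p = 7.61e-17, adjusted p = 0.102 with an estimated correlation). Examples were Mki67 (1.96, SE 0.28), Top2a (2.03, SE 0.36) and Foxm1 (1.53, SE 0.25). Dendritic cell genes rose in 6 of 14 cases (9 adjusted over the list alone), among them Cd74 (1.89, SE 0.18) and H2-Ab1 (1.62, SE 0.20). Their median was 1.1 (camera adjusted p = 5.74e-09, adjusted p = 0.0919 with an estimated correlation). Of 12 adipose expansion markers 7 rose and 1 was lowered (8 and 1 adjusted over the list alone). Their median was 0.69 (camera adjusted p = 9.02e-08, adjusted p = 0.0919 with an estimated correlation). Matrix genes had 10 of 27 raised and 1 lowered (12 and 1 adjusted over the list alone), led by Col6a2 (1.86, SE 0.21), Col15a1 (1.25, SE 0.18) and Sparc (1.22, SE 0.20). Their median was 0.62 (camera adjusted p = 3.06e-10, adjusted p = 0.102 with an estimated correlation).

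Macrophage genes had 4 of 19 raised (adjusted over the list alone, 8 raised and 1 lowered). Their median was 0.45 (camera adjusted p = 0.000306, adjusted p = 0.464 with an estimated correlation). Mpeg1 (1.45, SE 0.25) and Cd68 (1.06, SE 0.26) were among the raised genes, and without high-fat replicate 1 the list of macrophages had a median of 0.25. Lipid-associated macrophage genes had 5 of 15 raised and 1 lowered (7 and 2 adjusted over the list alone). Their median was 1.02 (camera adjusted p = 0.00474, adjusted p = 0.578 with an estimated correlation). Within that list Itgax (2.55, SE 0.36) and the fungal sugar receptor Clec7a (1.39, SE 0.31) rose. Trem2, a lipid receptor of these macrophages, was lowered from 47.5 ± 13.7 to 15.2 ± 3.40 CPM (-1.64, SE 0.34, adjusted p = 0.0146), a call lost without high-fat replicate 3 (adjusted p = 0.0722). T and NK cell genes had Cd3d raised (2.19, SE 0.59, adjusted p = 0.0401), 4 of 15 raised when adjusted over the list alone. Their median was 0.97 (camera adjusted p = 0.00129, adjusted p = 0.596 with an estimated correlation), and without high-fat replicate 2 the T and NK cells list was not called (median 0.81).

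Mesothelial genes were lowered in 11 of 15 cases and raised in 0 (14 lowered when adjusted over the list alone). Their median was -1.28 (camera adjusted p = 1.08e-12, adjusted p = 0.102 with an estimated correlation). Examples were the Wnt agonist Rspo1 (-1.17, SE 0.21), Krt19 (-2.03, SE 0.40), the transcription factor Wt1 (-1.11, SE 0.22) and Upk3b (-1.55, SE 0.34). Of 7 genes of ovary, oviduct and uterus Pgr, the progesterone receptor, was lowered (-3.00, SE 0.52, adjusted p = 0.00648), and 5 were lowered when adjusted over the list alone. Their median was -0.82 (camera adjusted p = 0.00449, adjusted p = 0.289 with an estimated correlation). Ribosomal protein genes were lowered in 6 of 29 cases (6 adjusted over the list alone, median -0.35, camera adjusted p = 4.90e-08, adjusted p = 0.596 with an estimated correlation). Lipogenesis genes were lowered in 2 of 18 cases (3 adjusted over the list alone), the desaturases Fads1 (-1.09, SE 0.18) and Fads2 (-0.70, SE 0.19). Their median was -0.34 (camera adjusted p = 0.00757, adjusted p = 0.74 with an estimated correlation). Without high-fat replicate 1 the de novo lipogenesis list was not called (median -0.27), and without high-fat replicate 3 its median was -0.54. Fasn stood at 8260 ± 559 and 6370 ± 2510 CPM (-0.37, SE 0.55, adjusted p = 0.719). Col1a1 (0.71, SE 0.15, adjusted p = 0.0159) and Mest (2.31, SE 0.50, adjusted p = 0.0167), an imprinted gene of growing fat, rose; 23.1% of the exon bases of Mest are shared with Copg2 on the other strand. Without control replicate 1 neither passed (adjusted p = 0.0661 and 0.07), and without high-fat replicate 3 Mest did not (adjusted p = 0.0663).

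The largest rises in transgenic tissue were in Art2a (7.18, SE 1.01; 196 counts on high-fat and 1 on control diet, ratio 195, 95% counting interval 34.6 to 7730) and Tph2 (4.73, SE 0.84). Next came Tm4sf19 (4.31, SE 1.20; 67 and 3 counts, ratio 22.2, interval 7.28 to 110) and Gas2l2 (4.19, SE 0.50). They were followed by Slc5a7 (3.91, SE 0.68), a choline transporter, Anks1b (3.90, SE 0.99), Ubd (3.51, SE 0.53), a ubiquitin-like modifier, Dusp15 (3.42, SE 0.45), Saa3 and Cdkl4 (3.26, SE 0.46). Anks1b stood at 8.18 CPM in high-fat replicate 3 against 0.959 and 0.576 CPM in the others. Without that library its change was 1.85 and not called (adjusted p = 0.163), as it was not without any 1 of the 3 controls. The change of Slc5a7 was 2.94 without the same library and still passed, and Tm4sf19 passed in 4 of the 12 fits without 1 library. The largest falls were in epithelial and other genes, namely Spint1 (-4.62, SE 1.30, adjusted p = 0.0458), Ckmt1 (-3.73, SE 0.87), Ptgds (-3.46, SE 0.81), Pak6 (-3.44, SE 0.93) and Shisal1 (-3.28, SE 0.55). Next were Mmd2 (-3.22, SE 0.81), Krt23 (-3.15, SE 0.77), Sp5 (-3.14, SE 0.62), Tspan8 (-3.09, SE 0.83) and Krt7 (-3.09, SE 0.76, adjusted p = 0.0285). The level of Krt7, a keratin of simple epithelia, was 64.4 ± 79.7 CPM in the transgenic control group, which holds the mammary-rich replicate 2, against 22.4 ± 10.6 CPM in wild-type controls. Spint1 stood at 6.14 ± 9.37 CPM in the same group, against 1.22 ± 0.967 CPM in wild-type controls. That library also carried Ckmt1 (6.49 CPM against 0.843 and 0.678 CPM in the other transgenic controls), Pak6 (4.14 against 0.347 and 0.497 CPM) and Tspan8 (6.7 against 1.17 and 0.595 CPM). Without it the changes were -1.56 for Spint1, -1.93 for Ckmt1, -1.50 for Pak6, -1.43 for Tspan8, -1.27 for Krt7 and -2.34 for Krt23, and none passed (adjusted p from 0.0718 to 0.324). These 6 calls were also lost without any 1 of the high-fat libraries. Spint1 and Pak6 passed in 3 of the 12 fits without 1 library and Tspan8 in 5. Ptgds did not pass without control replicate 1 or high-fat replicates 2 or 3, nor Mmd2 without control replicates 1 or 3 or high-fat replicates 2 or 3 (adjusted p up to 0.102 and 0.124). Shisal1 and Sp5 passed in all 12 such fits. Tph2 lies at chromosome 10, 115078641 to 115185022, and Gas2l2 at chromosome 11, 83421635 to 83429521 (GRCm38).

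Without transgenic control replicate 1, control replicate 2, high-fat replicate 1 or high-fat replicate 3, the 1445 diet calls became 572, 865, 912 and 543. The count was 826 without both mammary-rich libraries, 764 when only the 6 transgenic libraries were fitted, 2120 with DESeq2 and 1278 with limma-voom, while the authors' deposited table calls 1605 genes.

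The diet calls of the 2 genotypes overlapped. Of 113 genes raised in wild type and 892 raised in transgenic tissue 94 were shared, against 6.1 for independent lists (Fisher's exact test, p = 3.14e-101). Of 75 and 553 lowered genes 44 were shared, against 2.5 (Fisher's exact test, p = 9.06e-46). No gene was called in opposite directions, and the 2 comparisons have no library in common. Fisher's test takes genes as independent, which they are not, and both comparisons use the same estimate of each gene's spread. The p-values therefore do not measure how the overlap would repeat in other libraries. Of the 188 wild-type calls 186 had the same sign in transgenic tissue, with a median of 0.90 in the called direction. Of the 1445 transgenic calls 1389 had the same sign in wild type, with a median of 0.50 in the called direction against a median size of 0.92 in transgenic tissue. Genes picked for passing in a comparison tend to show larger values in it. Across 16550 genes, which are not independent replicates, the log2 changes correlated with a Pearson coefficient of 0.37 and a Spearman coefficient of 0.54, and 71.6% shared their sign.

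**Figure D3:**
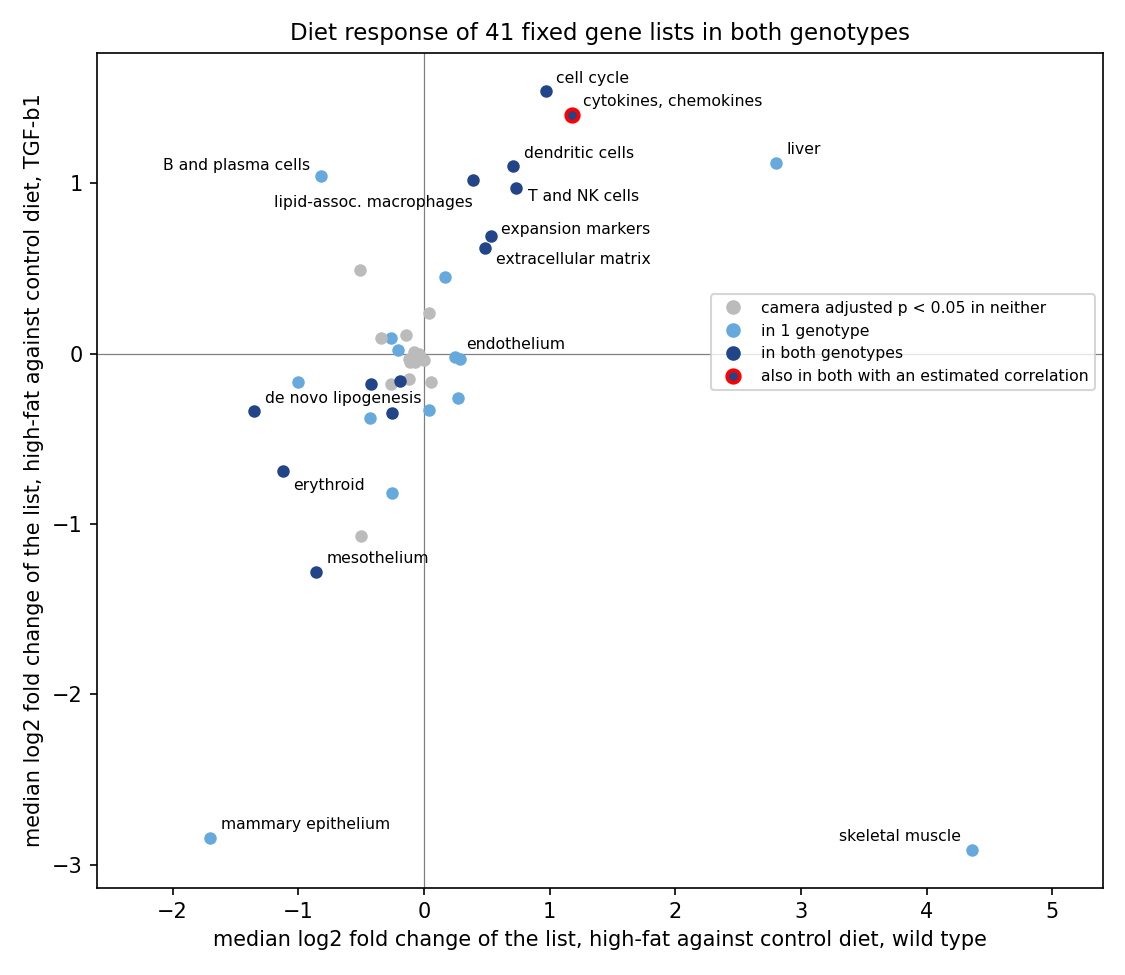
Median log2 fold change (high-fat against control diet) of each of 41 gene lists in wild type (x axis) and in TGF-b1 transgenic tissue (y axis), coloured by whether camera at its preset correlation called the list in neither, 1 or both genotypes. The cytokine and chemokine list (1.18 and 1.40) holds in both with an estimated correlation, mesothelial genes lie at -0.86 and -1.28, and muscle, mammary and liver lists follow the libraries rich in those transcripts.

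On control diet, transgenic adipose tissue differed from wild type in few genes by edgeR's test, 6, against 256 with DESeq2 and 151 in the authors' deposited table. Pcp4l1 rose from 1.78 ± 0.855 CPM in wild type to 11.4 ± 1.21 CPM in transgenic tissue (SD, n = 3 each; log2 2.68, SE 0.39, adjusted p = 0.0459). The protein kinase gene Pkn3 rose as well (0.88, SE 0.12, adjusted p = 0.0315). The 4 lowered genes were Npr3 (-0.93, SE 0.13, adjusted p = 0.0315), Fgf13 (-1.12, SE 0.15, adjusted p = 0.0315) and a further pair. These were Anxa1 (-0.88, SE 0.12, adjusted p = 0.0315), an anti-inflammatory phospholipid-binding protein, and Cybb (-0.86, SE 0.12, adjusted p = 0.0372), the catalytic subunit of the phagocyte NADPH oxidase. These 6 genes were all that passed edgeR's test, while 1816 had an unadjusted p under 0.05 against 828 expected by chance. A division of the same control-diet libraries into groups of 3 that mix the genotypes gave 8 calls. A count of 6 therefore does not set the genotypes apart. Camera called 18 of 41 lists (8 up, 10 down), and 0 with an estimated correlation. Groups of 3 that mix the genotypes gave up to 22 called lists. None of the 6 passed without wild-type control replicates 1 or 2, wild-type high-fat replicate 2, transgenic control replicates 1 or 2, or transgenic high-fat replicates 2 or 3 (adjusted p up to 0.236 for Pcp4l1). Npr3 lies at chromosome 15, 11839896 to 11907837, and Pcp4l1 at chromosome 1, 171173264 to 171196268 (GRCm38).

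Besides Npr3, the expansion markers Sfrp5 and Lep were each lower in all 3 transgenic than in all 3 wild-type libraries without passing edgeR's test. The authors' deposited DESeq2 table calls Lep (adjusted p = 4.18e-06) and not Sfrp5 (adjusted p = 0.271). Sfrp5 stood at 317 ± 178 against 101 ± 51.0 CPM (-1.65, SE 0.37, edgeR adjusted p = 0.147) and Lep at 1600 ± 351 against 745 ± 114 CPM (-1.1, SE 0.27, edgeR adjusted p = 0.185). Of the 12 genes of that list 1 was lowered over all genes and 4 when adjusted over the list alone. Their median was -0.21 (camera adjusted p = 0.00019, adjusted p = 0.274 with an estimated correlation). The cytokine and chemokine list had 0 of 15 calls by edgeR over all genes, 3 lowered when adjusted over the list alone, namely Ccl7 (-1.02, SE 0.22), Ccl2 (-1.1, SE 0.31) and Saa3 (-1.78, SE 0.54). Its median was -0.38 (camera adjusted p = 0.000363, adjusted p = 0.111 with an estimated correlation, fry adjusted p = 0.0091). Endothelial genes had 0 of 17 calls over all genes, 8 raised when adjusted over the list alone, including Vwf (0.73, SE 0.14) and Tie1 (0.42, SE 0.13). Their median was 0.36 (camera adjusted p = 2.78e-08, adjusted p = 0.227 with an estimated correlation). Smooth muscle and pericyte genes had 0 of 15 calls over all genes, 6 raised when adjusted over the list alone, including Myh11 (adjusted p = 0.00513 over the list alone) and Des (1.24, SE 0.30). Their median was 0.39 (camera adjusted p = 2.31e-05, adjusted p = 0.227 with an estimated correlation). B and plasma cell genes had 3 of 10 lowered when adjusted over the list alone. Their median was -1.13 (camera adjusted p = 9.45e-05, adjusted p = 0.427 with an estimated correlation). Skeletal and cardiac muscle genes had a median of 4.66 (camera adjusted p = 0.000176, adjusted p = 0.43 with an estimated correlation), beside the muscle-rich transgenic control replicate 3. Schwann cell genes had one of -0.74 (camera adjusted p = 0.00655, adjusted p = 0.439 with an estimated correlation), beside the Schwann-rich wild-type control replicate 1. Leaving out single libraries moved these medians. Without wild-type control replicate 1 the Schwann median was 0.04 and not called, the B and plasma cells median -0.70 and the expansion median -0.32. Without transgenic control replicate 3 the Schwann cells and nerve list was not called (-0.53), the muscle median was 0.87 and that of the adipose expansion markers on high-fat diet -0.08. The expansion median was -0.36 without transgenic control replicate 1 and -0.32 without its replicate 2. The cytokine median was -0.58 without transgenic control replicate 1, and the smooth muscle median 0.20 without wild-type control replicate 3.

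TGF-beta target genes had 0 of 21 calls by edgeR and a median of 0.09 on control diet (camera adjusted p = 0.203) and 0.08 on high-fat diet (camera adjusted p = 0.051). TGF-beta ligands, receptors and Smads had 0 of 20 calls on control diet, 2 raised when adjusted over the list alone, the co-receptor Eng (0.77, SE 0.16) and the inhibitory Smad6 (0.80, SE 0.23). Their median was 0.11 (camera adjusted p = 0.0171, adjusted p = 0.356 with an estimated correlation). It was 0.23 without wild-type control replicate 3, and the call was lost without wild-type control replicate 1 (median 0.07) and without transgenic control replicate 3 (median 0.02). Smad7 (0.44, SE 0.24, adjusted p = 0.524), a direct target of the pathway, did not pass. Irs2, an insulin receptor substrate, was the gene of the insulin signalling list with the smallest p (0.93, SE 0.15, adjusted p = 0.0637) and the 1 gene of 17 raised when adjusted over that list alone.

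The number of control-diet transgene calls became 1, 0, 58, 0, 0, 0, 35, 1, 0 and 0 without wild-type control replicates 1, 2 and 3, wild-type high-fat replicate 2, transgenic control replicates 1, 2 and 3, and transgenic high-fat replicates 1, 2 and 3. It was 1 without both mammary-rich libraries, 16 without both muscle-rich libraries, 0 when only the 6 control-diet libraries were fitted, 256 with DESeq2, 8 with limma-voom and 269 with no filter on low counts, while the authors' deposited table calls 151 genes.

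On high-fat diet, no gene passed edgeR's test between transgenic and wild-type tissue. The duration of feeding is not assigned to libraries and could differ between these groups. Camera called metabolic lists up, with medians from 0.20 for lipolysis to 1.78 for thermogenic genes, and no list held when the correlation was estimated (smallest adjusted p = 0.134 with an estimated correlation). Pnpla2, the adipose triglyceride lipase, stood at 2190 ± 44.1 CPM in wild type and 3190 ± 202 CPM in transgenic tissue (SD, n = 3 each; log2 0.54, SE 0.13, adjusted p = 0.712). The genes with the smallest p were Zkscan16 (-2.45, SE 0.46), the protease inhibitor Slpi (-1.71, SE 0.33), the neurotrophic factor receptor Cntfr (1.62, SE 0.33), Fgl2 (-0.76, SE 0.16) and Prr15 (-1.77, SE 0.38), each with an adjusted p of 0.712 by edgeR. The authors' deposited DESeq2 table calls Slpi (adjusted p = 6.89e-15), Pnpla2 (adjusted p = 0.000127), Fgl2 (adjusted p = 0.000483), Cntfr (adjusted p = 0.000799) and Prr15 (adjusted p = 0.0253). It gives no adjusted p for Zkscan16. By edgeR 0 genes passed, with 1114 at an unadjusted p under 0.05 against 828 expected by chance. Limma-voom called 0 and DESeq2 called 9, while the authors' deposited table calls 73. Camera called 19 of 41 lists (13 up, 6 down), and 0 with an estimated correlation. Dividing the same high-fat libraries into groups of 3 that mix the genotypes gave up to 22 called lists. The number called therefore does not set the genotypes apart. Without a filter on low counts edgeR called 5 genes, named after their values were seen as Clstn3, Cntfr, Pdk4, Slc39a8 and Slpi.

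Fatty acid oxidation genes all had a positive log2 difference, 17 of 17. Their median was 0.51 (camera adjusted p = 2.68e-14, adjusted p = 0.214 with an estimated correlation). Adjusted over the list alone 10 were raised, among them the dehydrogenases Acads (0.37, SE 0.10) and Acadm (0.51, SE 0.17), the carnitine palmitoyltransferase Cpt2 (0.57, SE 0.19) and the nuclear receptor Ppara (1.09, SE 0.35), and 0 over all genes by edgeR. Oxidative phosphorylation genes were positive in 26 of 26 cases, with 4 raised when adjusted over the list alone. Their median was 0.32 (camera adjusted p = 5.35e-14, adjusted p = 0.333 with an estimated correlation). Thermogenic adipocyte genes had 2 of 14 raised when adjusted over the list alone, Pdk4 (1.69, SE 0.41) and Ebf2 (0.38, SE 0.11). Their median was 1.78 (camera adjusted p = 5.07e-08, adjusted p = 0.267 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, stood at 17.1 ± 29.3 CPM in wild type and 95.2 ± 115 CPM in transgenic tissue (2.48, SE 1.75, adjusted p = 0.823). Lipolysis genes had a median of 0.20, with Pnpla2 raised when adjusted over the list alone (camera adjusted p = 0.00039, adjusted p = 0.134 with an estimated correlation, fry adjusted p = 0.0254). Triglyceride synthesis and storage genes had a median of 0.27 (camera adjusted p = 1.51e-05, adjusted p = 0.243 with an estimated correlation). Cell cycle genes had one of 0.39 (camera adjusted p = 4.82e-06, adjusted p = 0.333 with an estimated correlation). Neither list had a member raised when adjusted over the list alone. Mesothelial genes were negative in all 15 cases. Their median was -0.77 (camera adjusted p = 3.42e-11, adjusted p = 0.214 with an estimated correlation). By edgeR 0 of them were called, over all genes or adjusted over the list alone. Cytokine and chemokine genes had a median of -0.48 and 0 of 15 calls (camera adjusted p = 0.00283, adjusted p = 0.155 with an estimated correlation). Liver genes had a median of -1.80 and 3 of 8 lowered when adjusted over the list alone (camera adjusted p = 0.0221, adjusted p = 0.472 with an estimated correlation), beside the liver-rich wild-type high-fat replicate 2.

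Transgenic high-fat replicate 1 stood apart in the lists of fatty acid oxidation (mean 8.06 on the log2(CPM + 1) scale, against 7.48 in both other replicates), oxidative phosphorylation (7.94 against 7.44 and 7.41) and thermogenic genes (4.94 against 3.48 and 3.63). Wild-type high-fat libraries lay at 7.10 to 7.32, at 7.13 to 7.45 and at 2.00 to 3.68 in these lists, so wild-type replicate 3 reached or passed transgenic replicates 2 and 3 in the last pair of lists. Without transgenic replicate 1 the medians were 0.25, 0.14 and 0.46, and camera still called the lists at its preset correlation. Ucp1 was 228 CPM in that library. Without it the cytokine median was -0.30, without transgenic replicate 3 the mesothelial median was -0.45 and the cell cycle median 0.64, and without wild-type replicate 2 the liver median was -0.23 and not called. The liver list was also not called without transgenic replicate 2 (-1.96).

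The transgene effects on the 2 diets, which share no library, overlapped at unadjusted p-values and correlated little. Across 16550 genes the log2 differences correlated with a Pearson coefficient of -0.06 and a Spearman coefficient of 0.16, and 58.1% shared their sign. At an unadjusted p under 0.05, 102 genes were raised on both diets against 32.3 for independent lists (Fisher's exact test, p = 6.89e-26), and 61 were lowered on both against 28.5 (Fisher's exact test, p = 1.92e-08), while 13 and 19 of the genes raised and lowered on control diet went the other way on high-fat diet. Genes are not independent, and both comparisons use the same estimate of each gene's spread. Some overlap above the value for independent lists can come from that alone, so these p-values overstate the evidence.

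The genotype by diet interaction tested whether the diet effect differed between genotypes, and no gene passed. The labels do not assign the duration of high-fat feeding, so a duration that differed between genotypes could not be told apart from an interaction. The smallest p-values belonged to Fgf13 (1.22, SE 0.21), Pcp4l1 (-3.12, SE 0.55), the glial and adipocyte calcium-binding protein S100b (2.24, SE 0.42), Tmem45b (1.63, SE 0.31) and the cannabinoid receptor Cnr1 (-1.27, SE 0.25), each with an adjusted p of 0.557. S100b stood at 8.38 ± 2.86, 8.82 ± 1.12, 3.05 ± 0.893 and 15.2 ± 5.36 CPM in wild type on control diet, wild type on high-fat diet, transgenic on control diet and transgenic on high-fat diet (SD, n = 3 each). The larger Lep change in transgenic tissue was not shown to differ from that in wild type (interaction 1.12, SE 0.38, adjusted p = 0.781). The same held for Sfrp5 (1.35, SE 0.52, adjusted p = 0.817), Trem2 (-1.25, SE 0.48, adjusted p = 0.817) and Tgfb1 (-0.07, SE 0.12, adjusted p = 0.972). By edgeR 0 genes passed, with 929 at an unadjusted p under 0.05 against 828 expected by chance, limma-voom called 0 and DESeq2 called 23. Without a filter on low counts edgeR called 53, and without wild-type control replicate 3 it called 8. Camera called 24 of 41 lists (14 up, 10 down), and 0 with an estimated correlation (smallest adjusted p = 0.244 with an estimated correlation).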

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

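The fit without the mammary-rich control of each genotype and the tests of sequencing depth, of the covariance of effects, of alike dilution of cell types, of mammary transcripts beside lipogenic genes and of a fasted state were chosen after the results were seen. Each gene list here stood out because its diet effect differed between the genotypes by camera's test of the interaction at the preset correlation, and none of them held with an estimated correlation (smallest adjusted p = 0.244 with an estimated correlation).

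Among metabolic lists the median interaction was 0.99 for de novo lipogenesis, 0.33 for triglyceride synthesis and droplet storage, 0.32 for fatty acid oxidation, 0.24 for oxidative phosphorylation, 0.75 for thermogenic adipocyte genes, 0.17 for adipose expansion markers, 0.44 for cholesterol biosynthesis and 0.43 for the glucocorticoid and fasting response. Among immune lists it was 0.22 for macrophages, 0.23 for dendritic cells, -0.40 for the interferon response and 1.89 for B and plasma cells. The B cell receptor genes Cd79a (2.12, SE 0.60) and Cd79b (1.92, SE 0.54) passed when adjusted over the list alone and not over all genes (edgeR adjusted p = 0.736 each). Among stromal and other tissue lists it was -0.24 for endothelium, -0.27 for smooth muscle and pericytes, -0.39 for mesothelium, -0.55 for ovary, oviduct and uterus, 1.05 for Schwann cells, -1.21 for liver and -7.39 for skeletal and cardiac muscle. The weakest median of each list with 1 library left out came without wild-type control replicate 1 for de novo lipogenesis (0.53) and Schwann cells (0.29), and without its replicate 2 for triglyceride synthesis (0.18), ovary (-0.35), the cell cycle (0.34) and ribosomal proteins (-0.04). It came without wild-type control replicate 3 for expansion markers (0.08), without wild-type high-fat replicate 2 for liver (-0.08) and without its replicate 3 for muscle (-1.57). It came without transgenic control replicate 1 for dendritic cells (0.13) and the unfolded protein response (-0.15), without its replicate 2 for the circadian clock (0.09) and the interferon response (-0.21), and without its replicate 3 for TGF-beta ligands (-0.10), endothelium (-0.12) and the fasting response (0.37). Without transgenic high-fat replicate 1 it was 0.07 for fatty acid oxidation, 0.06 for oxidative phosphorylation, 0.24 for thermogenic genes, 0.10 for macrophages and -0.13 for smooth muscle. Without transgenic high-fat replicate 3 it was 0.23 for cholesterol biosynthesis, -0.10 for mesothelium and 1.30 for B cells. The muscle, liver and Schwann values also stand beside libraries rich in those transcripts, namely muscle in wild-type high-fat replicate 3 and transgenic control replicate 3, liver in wild-type high-fat replicate 2 and Schwann cells in wild-type control replicate 1. For the remaining lists it was -0.18 for TGF-beta ligands, receptors and Smads, 0.57 for the cell cycle, 0.26 for the circadian clock, -0.29 for the unfolded protein response and -0.12 for ribosomal proteins. Of 60 splits of the libraries drawn within diet from 200 possible, 1 (the real split) gave as many as 24 lists, with 21 the highest other. That share is under 0.05 for the count at the preset correlation with all 12 libraries. Shuffling genotype within diet also breaks a transgene effect that is alike on both diets. These splits therefore cannot exclude chance for the interaction alone. The count of 24 lists fell to 17 without transgenic control replicate 3 and to 0 with an estimated correlation. Of the 24 lists 8 kept their call in every fit without 1 library, while 16 lost it in at least 1. For genes the real count was 0, which all 60 splits match by construction (highest other 2), so that test says nothing about chance.

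More genes passed the test for diet in transgenic than in wild-type libraries, 1445 against 188 by edgeR, 764 against 226 when only the 6 libraries compared were fitted, 2120 against 847 by DESeq2, 1278 against 699 by limma-voom and 1605 against 1011 in the authors' deposited tables. A larger spread between wild-type libraries over all genes was excluded, because their biological coefficient of variation was 17.3% against 20.2% for transgenic libraries. That is 1 value per genotype over all genes, so it cannot exclude a larger wild-type spread in the genes that respond to diet. Lower depth was excluded by mean totals of 21.0 and 20.8 M counts. Epithelial transcripts in wild-type control replicate 1, named mammary after their list, were excluded as the whole reason. The wild-type count without that library, 2, is hard to read alone (13, 269, 9, 0 and 17 without control replicates 2 and 3 and high-fat replicates 1, 2 and 3). Without the mammary-rich control of each genotype, however, the counts were 32 against 826, and the lowest transgenic count without 1 transgenic library was 543. A shift of transgenic controls away from high-fat libraries stayed open. The covariance of the control-diet transgene effect with the wild-type diet effect was 0.0193, below the lowest of 100 simulations without effects (0.0341). It was 0.0307, 0.0324, 0.0287, 0.0281 and 0.00125 without wild-type control replicates 1 and 2 and transgenic control replicates 1, 2 and 3. Each of these lay below the lowest simulated there (0.0495, 0.0499, 0.0327, 0.0331 and 0.0335). Without wild-type control replicate 3 it was 0.0542, above the lowest simulated (0.0508). The simulations drew each gene independently, while genes of real libraries vary together. Their range is therefore too narrow to decide on such a shift. A response to diet that differs with genotype may remain, although no gene's interaction passed edgeR's test (929 at an unadjusted p under 0.05, 23 by DESeq2, 0 by limma-voom). The labels do not assign the duration of high-fat feeding to libraries. A duration that differed between the genotypes could not be told apart from such a response.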

How the results depend on the processing

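The fits without the 2 mammary-rich or the 2 muscle-rich libraries were added after the data were seen. Counts are given for diet in wild type, diet in transgenic tissue, the transgene on control diet, the transgene on high-fat diet and the interaction, and were 188, 1445, 6, 0 and 0 by edgeR. RLE and upper-quartile factors and a filter of at least 1 CPM in 6 libraries kept each count within 1.5 times, and all 161 results for named genes kept their side of the threshold under both other scalings. No result changed its direction past the threshold under any alternative run.

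At an adjusted p under 0.01 the first 3 counts were 3 (Ccl7, Jag1 and Stard10, of which Jag1 and Stard10 were chosen after their values were seen), 307 and 0, and with an absolute log2 change of at least 1 they were 76, 646 and 2 (Fgf13 and Pcp4l1). With no filter on low counts the wild-type diet, both transgene and interaction counts were 683, 269, 5 and 53, and with DESeq2 847, 256, 9 and 23. Limma-voom moved the wild-type diet count alone, to 699. Fitting only the 6 libraries compared gave 764 for diet in transgenic tissue and 0 for the transgene on control diet. Without the mammary-rich libraries the wild-type diet, transgenic diet, control-diet transgene and interaction counts were 32, 826, 1 and 1 (Gm42226 in both of the last, chosen after its values were seen). Without the muscle-rich libraries the wild-type diet count was 23 and the control-diet transgene count 16. Fewer libraries were tested in these fits, and for the other settings the cause was not tested. At an unadjusted p under 0.05, 1641 diet calls and 163 transgene calls were shared.

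With the replicate block the wild-type diet count was 99 and the control-diet transgene count 0. Pairing by replicate number was not seen. The 18 same-number pairs correlated with -0.111 to 0.265 (4 above 0.1), on average 0.02 against -0.01 for other pairs. Of 12 libraries 4 correlated best with their own number. With 3 libraries per group these values cannot exclude a weak pairing.

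Leaving out each library in turn gave 0 to 269 genes for diet in wild type (0 without high-fat replicate 2, 269 without control replicate 3), 543 to 1504 for diet in transgenic tissue (543 without its high-fat replicate 3), 0 to 58 for the transgene on control diet (58 without wild-type control replicate 3), 0 to 0 for the transgene on high-fat diet (edgeR, 1114 at an unadjusted p under 0.05, 9 by DESeq2, 0 by limma-voom) and 0 to 8 for the interaction. List counts ran from 21 to 25, 14 to 19, 13 to 21, 17 to 23 and 17 to 25 in the same order. Of named called genes, 0 of 24, 15 of 28 and 0 of 6 kept their call in all 12 such fits of the first 3 comparisons. Lists called with an estimated correlation numbered 1, 1, 0, 0 and 0, and by fry 6, 9, 1, 1 and 0.

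On simulated counts a 2-fold change was recovered for 68.7% of genes for diet in wild type and 37.3% for the interaction, so smaller interactions were mostly below what 3 libraries per group can show. With Ttr, at 0 counts in wild-type controls, set to the floor of 3 counts, the liver medians were 2.80 for diet in wild type and -1.21 for the interaction, as fitted. With Krt5, at 0 counts in wild-type high-fat libraries, treated alike, the mammary interaction median was -1.33 in place of -0.30, and that list was not called (camera adjusted p = 0.616).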

Other observations

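Of the tests here, the fit without the mammary-rich libraries and those of alike dilution, of mammary transcripts beside lipogenic genes and of a fasted state were chosen after the results were seen. In transgenic tissue on high-fat diet, oxidative stress genes moved both ways: Slc7a11, the cystine transporter subunit, rose (log2 2.33, SE 0.34, edgeR adjusted p = 0.00285), as did the heme oxygenase Hmox1 (1.13, SE 0.25, adjusted p = 0.0192), while the plasma peroxidase Gpx3 was lowered (-2.08, SE 0.32, adjusted p = 0.00347). The list had 2 of 15 genes raised and 2 lowered (3 and 5 when adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.439). Unfolded protein response genes had 2 of 18 lowered, Xbp1 (-0.70, SE 0.15) and Pdia4 (-0.53, SE 0.12), 3 when adjusted over the list alone, and a median of -0.33 (camera adjusted p = 0.00246, adjusted p = 0.582 with an estimated correlation), or -0.18 without transgenic control replicate 1. Lpl, the lipoprotein lipase that takes up circulating triglyceride (0.76, SE 0.15, adjusted p = 0.0128), and the glycerol channel Aqp7 (0.62, SE 0.14, adjusted p = 0.0192) rose in the same comparison.

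Mesothelial markers were lower on high-fat diet, with medians of -0.86 in wild type and -1.28 in transgenic tissue. The endothelial and progenitor medians lay above the mesothelial one by 1.11 and 0.73 in wild type and by 1.25 and 1.24 in transgenic tissue. The lowest bootstrap bound was 0.33 against a margin of 0.3, but the bootstrap resampled genes and not libraries. Per library, wild-type mesothelial means were 5.54 to 6.16 on control and 5.01 to 5.36 on high-fat diet, and endothelial means 5.36 to 5.58 and 5.7 to 5.8. In transgenic tissue they were 5.71 to 6.16 and 3.79 to 4.95, and 5.8 to 5.88 and 5.67 to 5.95. These values argue against alike dilution of all non-adipocyte cells by larger adipocytes. Epithelial transcripts of the 2 mammary-rich control libraries were excluded as the whole reason, since the medians were -0.68 in wild type and -1.25 in transgenic tissue without them. Reproductive tissue was not tested and stays open, as the ovary, oviduct and uterus list had lower means on high-fat diet in transgenic tissue too (2.10, 2.11 and 1.89 against 2.98, 2.46 and 2.66 on the log2(CPM + 1) scale). A smaller share of mesothelium in the sampled fat, through dissection or growth of the depot, may also remain and was not tested.

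Lipogenic genes were lower in wild-type control replicate 3 than in replicates 1 and 2, in 18 of 18 genes, with a median difference of -1.98. Transcripts of the mammary list were excluded as the reason for the gap to replicate 2, since its mean of that list minus that of replicate 3 was -0.33. They were not excluded for the gap to replicate 1, whose mean of that list was 2.59 against 1.08 in replicate 3. The glucocorticoid and fasting list was higher in replicate 3, by a median of 0.23 over 14 genes, at the 99.8 percentile of random lists matched on expression (95th percentile 0.11). Random lists do not keep the joint variation of related genes, so the percentile cannot decide whether the mouse was fasted. That explanation was found and tested on the same library and stays open. The list's mean was 6.56 in replicate 3, and 6.54 and 6.58 in transgenic high-fat replicates 1 and 3. The labels do not give the feeding state or the diet duration of any library, and no other biological explanation was tested.

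For splits of 6 libraries, 10 are possible and the share cannot go under 0.1. For genes, 1 of 10 splits gave as many as the real 188 for diet in wild type (highest other 0), 1 of 10 as many as 1445 in transgenic tissue (highest other 0), 2 of 10 as many as 6 for the transgene on control diet (highest other 8, from wild-type control replicates 1 and 2 with transgenic control replicate 2) and 10 of 10 as many as 0 on high-fat diet (highest other 1), which a real count of 0 fixes in advance and so tests nothing. For lists, 1 of 10 gave as many as the real 23 (highest other 20), 3 as many as 17 (highest other 19), 2 as many as 18 (highest other 22) and 3 as many as 19 (highest other 22), in that order.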
